A study of Mus musculus with 18 samples.

How the data were processed

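Messenger RNA and tRNA-derived small RNA (tsRNA) were measured in lung tissue of mice in 3 groups of 3 libraries each, which makes 9 libraries per RNA type and 18 in all. The groups and replicate numbers were taken from the sample labels. Per the labels, the treated group received BMSCs in 100 µl of phosphate-buffered saline by tail vein, and the control and COPD model groups received saline alone. Total RNA was extracted with Trizol, with 1.5 µg as input per sample. For mRNA, poly(A) RNA was enriched with oligo dT and a stranded kit was used. For tsRNA, the RNA was pretreated to remove modifications that block reverse transcription or adapter ligation, and small RNA libraries were then made. Per the submitters' processing notes, FastQC, cutadapt, StringTie and Bowtie were used with the mouse build mm10. Their versions and roles, and whether strand was used in assigning reads, are not given in the sources used here.

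The mRNA values are FPKM per the file headers, scaled by the authors to transcript length and to the reads of each library before they were deposited. The deposited table held 13384 genes, and in each of them at least 1 group mean was 0.5003 FPKM or more, so genes low in all groups had been removed. The low FPKM values were searched for steps of whole reads, which would make the ratio of 2 libraries pile up at a common value over genes under 0.3 FPKM in both. In control over BMSC-treated libraries 81 of 892 genes for number 1, 11 of 138 for number 2 and 7 of 66 for number 3 lay within 0.02 log2 of the commonest ratio. In the same order 31, 4 and 1 genes lay as close to a ratio 1 log2 higher, which 2 reads against 1 would give. No smooth spread was set beside these counts, so whether they are steps was not decided, and the depth of the mRNA libraries is unknown. The tsRNA table held raw read counts per the file headers, which the authors deposited without normalization, and a second deposited table held the same tsRNAs in CPM, scaled to the mapped reads of each library. Every listed tsRNA reached 20.15 CPM or more in at least 1 library. The counts divided by the CPM gave 1 total per library, and the listed tsRNAs made up 42.6% to 70.58% of these totals. A floor of 3 counts, the limit that a count of 0 allows, corresponds to 1.12 to 3.36 CPM, and it covers counting error only, since reads were not collapsed to molecules. Listed tsRNAs were 14 to 40 nucleotides long. No value column was left unassigned to a sample. No libraries held identical values.

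Gene symbols were taken from the mRNA table. Of its gene IDs, 13362 were in the table of gene names, and 12954 genes had coordinates in the RefSeq annotation of GRCm38.p6, which is mm10. A set of 24 genes shared 12 symbols, and these were kept apart by ID. Genes that overlap or share exons, such as those of the Ugt1a locus, and mitochondrial genes with nuclear copies may share reads.

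Comparisons were fixed before the data were examined: COPD model against control, BMSC-treated against COPD model, BMSC-treated against control, and the reversal of the first by the second. Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were tested, which left 11765. log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend and all 9 libraries in one fit. Benjamini-Hochberg adjusted p under 0.05 made a call. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. A set of 40 gene lists had been fixed for lung cell types, other tissues that a lung piece can hold, smoke responses, stress and RNA metabolism. limma's camera with a preset correlation of 0.01 tested 39 of them against all other genes. The list of mast cell, basophil and eosinophil markers had 1 of 11 genes above the filter and was not tested. Counts of members passing are given over all genes tested and adjusted over the list alone. tsRNA counts were tested with edgeR 4.0.16 (quasi-likelihood, TMM factors, filterByExpr, library size from the listed tsRNAs), which kept 191 of 193 tsRNAs at a common biological coefficient of variation of 0.5448. Summed counts of the 9 structural types and 32 parent tRNA classes were tested with the same factors. For the reversal, which shares the COPD model libraries between both comparisons, 100 sets with no group effect were simulated, and 100 more that kept the correlation of same-numbered control and BMSC-treated libraries, chosen after seeing the data. Shares per library were compared by two-sided exact permutation tests, and between same-numbered control and BMSC-treated libraries also by exact paired ones, added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

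Genes were named by a rule fixed in advance. In each mRNA comparison these were the 8 largest and 8 most negative called changes with groups that did not overlap, filled to 8 by smallest p as not passing, with 4 members of each called list and at most 2 of each other list, by smallest p. Genes known only by a Gm number, a Rik name or no symbol were counted under this rule. For tsRNAs the rule took 5 per direction, filled to 3. Not every gene that the rule takes is reported here. The predicted genes Gm20521 and Gm17606, the most abundant tsRNA and the libraries that stood apart were singled out after their values were seen.

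The tests were tried on simulated data with known changes. Of 100 genes changed 2-fold among 11765, 3%, 7% and 3% were recovered in the 3 comparisons in the order above, and of 100 changed 4-fold 24%, 39% and 28%. False calls among unchanged genes numbered 3, 4 and 1. All 5 lists changed 2-fold were recovered in each comparison, with 0, 0 and 2 false list calls. Genes were drawn independently of each other, so these list counts do not show how the test fares where members of a list are correlated. Of 20 tsRNAs among 191, 5%, 0% and 0% were recovered at 2-fold and 50%, 35% and 35% at 4-fold, with 1, 0 and 0 false calls.

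Replicate numbers came from the labels, which give them no meaning. Deviations from the group means were correlated between same-numbered libraries. Control and BMSC-treated libraries met the limit of 0.1 for all pairs, with 0.63, 0.19 and 0.5 for mRNA and 0.72, 0.74 and 0.2 for tsRNA, so the numbers were taken to pair these groups, from the data alone. In the comparisons that include the COPD model not all pairs met it.

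Alternatives were other pseudocounts (0.1 and 0.01), other filters (a mean FPKM above 0, a mean FPKM of at least 5), quantile normalization, centring on the median, fits of only the 6 libraries compared, the replicate block, robust moderation, an estimated correlation, fry, an unadjusted p under 0.05 with at least 1.5-fold, an adjusted p under 0.1, and leaving out each library. For tsRNAs they were relative log expression factors, library size alone, library sizes implied by the CPM, other filters (any count, at least 10 CPM in 3 libraries), DESeq2 1.42.0 and limma on log2(CPM + 1). Chosen after seeing the data were fits without control 1 and BMSC-treated 1, FPKM rescaled to an equal sum over genes other than Scgb1a1 and the mitochondrial genes, both together, tsRNA fits without the shallowest library of each group, and that library as a covariate.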

Results

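Lung tissue of mice was profiled to ask how mesenchymal stem cells, named BMSCs in the labels, alter messenger RNA and tRNA-derived small RNA (tsRNA) in a model of chronic obstructive pulmonary disease (COPD), a smoking-related narrowing and destruction of the airways and alveoli. There were 3 groups of 3 libraries for each RNA type. The control group received phosphate-buffered saline. The COPD model group was exposed to cigarette smoke, was injected intraperitoneally with cigarette smoke extract and also received saline. The BMSC-treated group was the same model given BMSCs by tail vein. tsRNAs are fragments cleaved from mature or precursor tRNAs, named by the part of the tRNA they come from. The 9 mRNA libraries listed 13384 genes in FPKM, with an unknown depth. The 9 tsRNA libraries listed 193 tsRNAs, with 440448 to 1742029 listed counts each, out of library totals of 893028 to 2679933 reads implied by the deposited counts and CPM. The labels do not say that each library came from a separate mouse, so p-values measure only the spread between these samples.

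Transcripts of the mitochondrial genome and of Scgb1a1, the secretoglobin that is the main secretory product of club cells, made up most of the FPKM in the mRNA libraries. The 13 listed mitochondrial genes held 67.1% ± 21.2 (SD, n = 3) of the FPKM in control lungs, 27.4% ± 3.16 (SD, n = 3) in COPD model lungs and 72.9% ± 18.4 (SD, n = 3) in BMSC-treated lungs. Scgb1a1 alone held 10.2% ± 9.01, 37.1% ± 3.58 and 4.59% ± 2.84 (SD, n = 3 each). The COPD model libraries did not overlap either other group in either share, with an exact permutation p of 0.1 in each comparison, two-sided, which is the smallest that 3 against 3 libraries can give. Between control and BMSC-treated libraries the unpaired exact permutation p was 0.7 for the mitochondrial share and 0.5 for the Scgb1a1 share. Same-numbered libraries of these groups deviated together, and within the 3 pairs the mitochondrial share was higher after BMSCs each time, at 92.2%, 70.8% and 55.6% against 89.2%, 65.1% and 46.9%. The exact paired permutation p, chosen after the values were seen, was 0.25, the smallest that 3 pairs can give. The Scgb1a1 share was higher in 1 pair and lower in 2 (exact paired p = 0.5). These shares set the level of all other genes, because FPKM is scaled to the library: the median log2 change of the 11765 genes tested was 0.66 for COPD model against control, -0.75 for BMSC-treated against COPD model and -0.10 for BMSC-treated against control. A pair of libraries stood apart within their groups. Control 1 and BMSC-treated 1 had mitochondrial shares of 89.2% and 92.2% and listed 1038 and 1193 genes at 0, against 107 to 201 in the other 7 libraries. In the same libraries Foxj1, the master regulator of motile cilia, stood at 1.33 and 3.42 FPKM, against 36.7 to 100.2 in the others.

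**Figure D1:**
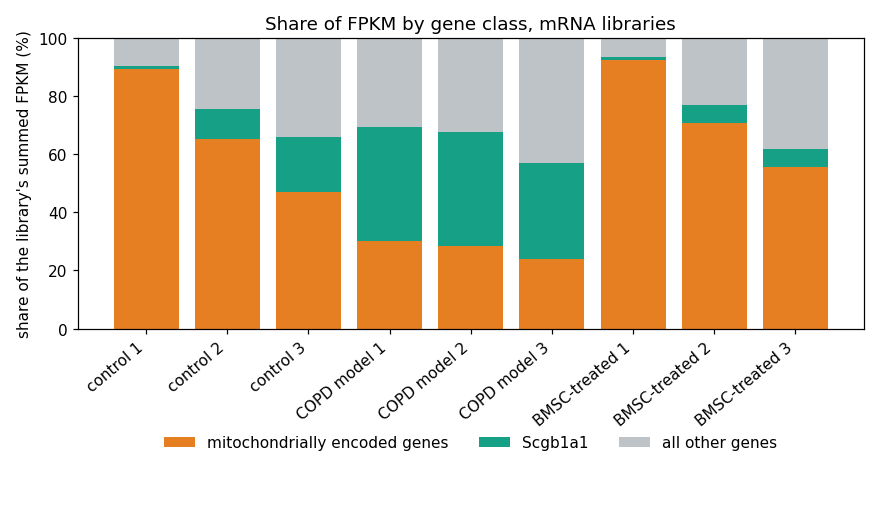
Share of the summed FPKM of each mRNA library (vertical axis, percent) held by mitochondrially encoded genes, Scgb1a1 and all other genes, for the 9 libraries (bars). The mitochondrial share lies between 23.91% and 30.04% in the COPD model libraries and between 46.9% and 92.2% in the others.

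The first comparison asked what cigarette smoke and smoke extract changed in the lung. Scgb1a1 (chromosome 19, 9083642 to 9087956, mm10) was higher in COPD model lungs, with a mean of 212700 ± 47100 FPKM (SD, n = 3) against 55590 ± 46700 in control, a log2 change of 2.62 ± 0.37 (SE). Plagl1, a zinc finger transcription factor (chromosome 10, 13090832 to 13131694), rose from 0.386 ± 0.123 to 6.99 ± 1.89 FPKM, a log2 change of 2.50 ± 0.54. Mitochondrially encoded subunits of the respiratory chain fell, with log2 changes of -1.78 ± 0.38 for mt-Nd5 and -1.50 ± 0.33 for mt-Nd4, both of complex I, -1.35 ± 0.31 for mt-Cytb of complex III and -1.40 ± 0.30 for mt-Co1 of complex IV. Ugt1a5, a glucuronosyltransferase gene, was listed at 0, 0 and 2.07 FPKM in control and at 9.12, 6.76 and 3.54 FPKM in the COPD model, and Ugt1a9 was listed at 0 in all control libraries and at 8.08, 0 and 3.93 FPKM in the COPD model. Genes of the Ugt1a locus (chromosome 1) share their last exons, so the division of reads among them is uncertain. These 8 genes and 1 predicted gene, Gm20521, which was lower, made 9 calls at an adjusted p under 0.05 by limma with Benjamini-Hochberg adjustment, 4 of them up and 5 down. The adjusted p was 3.23e-06 for Scgb1a1 and ranged from 0.0215 to 0.0359 for the others. At an unadjusted p under 0.05 and at least 1.5-fold, 748 genes were higher and 27 lower, and 2820 genes (24%) had groups that did not overlap, against 10% by chance for 3 against 3. Of the 2820, 2783 were higher and 37 lower, beside a median of all genes of 0.66 with 94.4% of genes above 0.

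Among genes that did not pass, those of smallest p included clock output factors. Tef had a log2 change of 3.17 ± 0.74 (adjusted p = 0.0534, limma) and Dbp, at 29.9, 53.4 and 46.9 FPKM against 0.693, 3.28 and 12.2 in control, one of 3.24 ± 0.78 (adjusted p = 0.0606, limma). Fkbp5, a glucocorticoid-induced chaperone of steroid receptors, had a mean of 6.86 ± 3.26 FPKM against 0.828 ± 0.325 (adjusted p = 0.174, limma). Arrb1, which encodes beta-arrestin, had a mean of 0.274 ± 0.140 FPKM against 3.90 ± 2.43 (adjusted p = 0.0606, limma). The calls were sensitive to scaling and to single libraries. With FPKM rescaled to an equal sum over genes other than Scgb1a1 and the mitochondrial genes, 0 of the 9 genes passed, and the log2 change was 1.85 for Scgb1a1 (adjusted p = 0.755, limma) and 2.03 for Plagl1 (adjusted p = 0.123, limma). The mitochondrial changes grew with this scaling, to -2.55 for mt-Nd5, -2.27 for mt-Nd4 and -2.16 for mt-Co1 (adjusted p = 0.755 each, limma). The error of Scgb1a1 was borrowed from other abundant genes: its moderated SD was 0.46 log2 where its own libraries had a pooled SD of 1.37. Leaving out 1 library at a time gave 1 to 47 calls, with 1 call without control 2 or BMSC-treated 1, 2 without COPD model 3, 3 without COPD model 2, 5 without control 1, 9 without BMSC-treated 2, 17 without COPD model 1 or BMSC-treated 3, and 47 without control 3. Scgb1a1 lost its call without BMSC-treated 1 (adjusted p = 0.224, limma), Plagl1 without control 2, COPD model 2 or COPD model 3 (0.211, 0.221 and 0.149), and mt-Nd5 without control 1, control 2, COPD model 3 or BMSC-treated 1 (0.517, 0.15, 0.149 and 0.224). BMSC-treated 1 is in neither group compared and enters through the shared spread, so that without it the log2 changes stayed at 2.62 for Scgb1a1 and -1.78 for mt-Nd5. Over all alternatives the adjusted p of limma ranged from 3.09e-28 to 0.995 for Scgb1a1 with 10 of 21 passing, from 0.00394 to 0.584 for Plagl1 with 10 of 20, and from 0.000241 to 0.922 for mt-Nd5 with 6 of 21. Without control 1 and BMSC-treated 1, 3 genes passed, Plagl1, Dbp and Maml2, the last of them named after its values were seen. In that fit the log2 change of Scgb1a1 was 1.43 (adjusted p = 0.2615, limma).

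**Figure D2:**
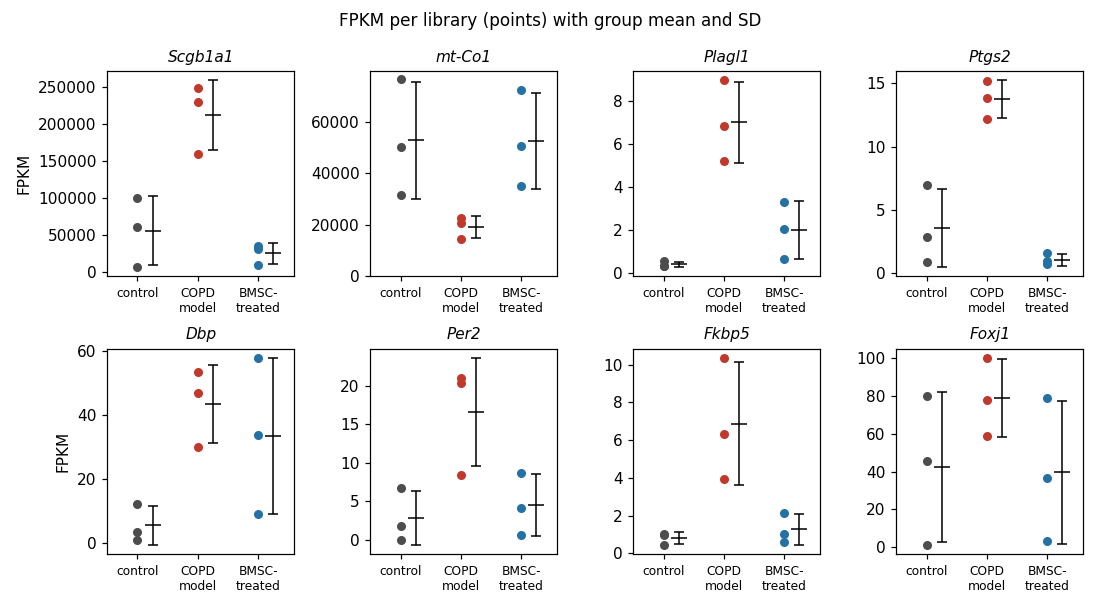
FPKM of 8 genes (vertical axes) in the 9 mRNA libraries by group, with points for libraries and bars for the group mean and SD. Scgb1a1 reaches 248500 FPKM in COPD model 1, mt-Co1 is lowest at 14300 FPKM in COPD model 3, and Foxj1 is at 1.33 FPKM in control 1.

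Of the 39 gene lists tested, 17 were called against all other genes by camera at an adjusted p under 0.05 in COPD model against control. The 6 lists that ranked above other genes were circadian clock genes, smooth muscle markers, NRF2 antioxidant targets, glucocorticoid-responsive genes, alveolar type 1 cell markers and ciliated cell markers. Circadian genes stood farthest up, with a median 1.32 log2 above that of all genes (adjusted p = 2.17e-09, camera, and adjusted p = 0.448 with an estimated correlation). Of 13 members, 0 passed over all genes tested and 10, all higher, passed when adjusted over the list alone, among them Per2 with 16.6 ± 7.04 FPKM against 2.83 ± 3.49 in control and Ciart with 8.11 ± 3.99 against 0.993 ± 1.12. Smooth muscle markers lay 1.23 above (adjusted p = 0.000374, camera, and adjusted p = 0.628 with an estimated correlation), and 6 of 8 passed over the list alone. They included the contractile genes Actg2 (log2 change 2.28 ± 0.81), Cnn1 (2.25 ± 0.81), Myh11 (2.01 ± 0.78) and Acta2 (2.10 ± 0.82). Glucocorticoid-responsive genes lay 0.78 above (adjusted p = 0.00143, camera, and adjusted p = 0.567 with an estimated correlation), and 4 of 9 passed over the list alone, among them Fkbp5 and Zbtb16 (1.76 ± 0.59). NRF2 targets, which detoxify electrophiles, lay 0.56 above (adjusted p = 0.0006, camera, and adjusted p = 0.768 with an estimated correlation), with 0 of 15 passing over the list alone and log2 changes of 1.73 ± 0.72 for Gsta2 and 1.81 ± 0.82 for Gsta4. Without control 1 and BMSC-treated 1 these log2 changes were 0.912 and 0.696. Alveolar type 1 markers lay 0.52 above (adjusted p = 0.0292, camera, and adjusted p = 0.784 with an estimated correlation), with 26.7 ± 12.0 FPKM against 6.62 ± 5.41 for Igfbp2 and 59.1 ± 18.1 against 25.9 ± 19.8 for the water channel Aqp5. Their log2 changes were 2.06 and 1.61 with all libraries, and 1.43 and 0.64 without control 1 and BMSC-treated 1. Ciliated markers lay 0.75 above (adjusted p = 0.0348, camera, and adjusted p = 0.866 with an estimated correlation), and that call rested on control 1: without it the direction turned and the adjusted p was 0.578. In the alveolar type 1 and ciliated lists 0 members passed over the list alone.

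The 11 lists that ranked below other genes were mitochondrially encoded genes and 10 lists mostly of blood and immune cells. The mitochondrial genes had a median 1.95 log2 below that of all genes (adjusted p = 1.26e-66, camera), and 4 of 12 passed over all genes and 10 over the list alone. Neutrophil markers lay 1.57 below (adjusted p = 7.42e-27, camera), with 79.0 ± 37.0 FPKM against 322.3 ± 217.9 for S100a9 and 64.5 ± 36.0 against 227.4 ± 151.1 for S100a8, which together form calprotectin. Erythroid genes lay 1.41 below (adjusted p = 9.84e-15, camera), with 169.5 ± 129.1 FPKM against 348.9 ± 173.9 for Hba-a1, an alpha globin. Platelet genes lay 1.03 below (adjusted p = 9.15e-17, camera, and adjusted p = 0.153 with an estimated correlation) and B cell markers 0.83 below (adjusted p = 1.5e-06, camera, and adjusted p = 0.376 with an estimated correlation), with Ppbp at 36.8 ± 20.8 FPKM against 95.2 ± 61.7 and Cd79a at 4.11 ± 3.92 against 5.76 ± 4.08. A further 6 lists had medians above 0 but below the shift of all genes, so that their rank and the sign of their own changes differed. Several of their members stood near 1 FPKM, where the log2(FPKM + 1) scale holds changes toward 0. Cd8a had a mean of 1.23 FPKM against 0.756 in control, yet its log2 change of 0.53 lay at -0.13 relative to all genes. Other members fell. Part of these ranks may therefore come from the scale. Relative to all genes these medians were -0.44 for inflammatory cytokines and chemokines, -0.46 for T and NK cell markers, -0.43 for interferon-stimulated genes, -0.53 for cardiac muscle, -0.50 for cell cycle and -0.36 for plasma cell genes. Their adjusted p values by camera were 2.14e-05, 0.000374, 0.000869, 0.00283, 0.00808 and 0.0286 in that order, and with an estimated correlation the adjusted p values were 0.0451, 0.628, 0.179, 0.628, 0.628 and 0.567. Ccl3, a macrophage chemokine, had 0.335 ± 0.335 FPKM against 1.40 ± 0.16, and Cxcl9, an interferon-induced chemokine, 0.509 ± 0.496 against 1.57 ± 0.83. In these 10 lists 0 members passed over all genes or over the list alone.

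With an estimated correlation the mitochondrial, neutrophil, erythroid and cytokine calls held, each at an adjusted p of 0.0451. The other 13 of the 17 calls were lost. fry, which asks whether a list moves on its own rather than against other genes, called 0 of 39 lists (smallest adjusted p 0.591). Rescaled FPKM ended the calls of cytokines (adjusted p = 0.17), T and NK cells (0.055), cardiac muscle (0.196), cell cycle (0.0751), plasma cells (0.162) and alveolar type 1 cells (0.257), and fits without control 1 and BMSC-treated 1 ended those of interferon-stimulated genes (0.383) and ciliated cells (0.669). Single libraries ended further calls, with adjusted p values without control 1 of 0.483 for interferon-stimulated genes. Without control 2 they were 0.158 for smooth muscle, 0.0503 for cardiac muscle with its direction turned, 0.185 for plasma cells and 0.211 for alveolar type 1 cells. Without control 3 they were 0.2 for glucocorticoid-responsive genes, 0.0812 for T and NK cells, 0.0721 for plasma cells and 0.113 for alveolar type 1 cells. Without COPD model 1 they were 0.121 for smooth muscle and 0.0998 for ciliated cells, and without COPD model 2 0.0517 for T and NK cells. Without COPD model 3 they were 0.114 for cardiac muscle, 0.414 for plasma cells and 0.536 for alveolar type 1 cells. Without BMSC-treated 1 they were 0.0714 for alveolar type 1 and 0.114 for ciliated cells.

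**Figure D3:**
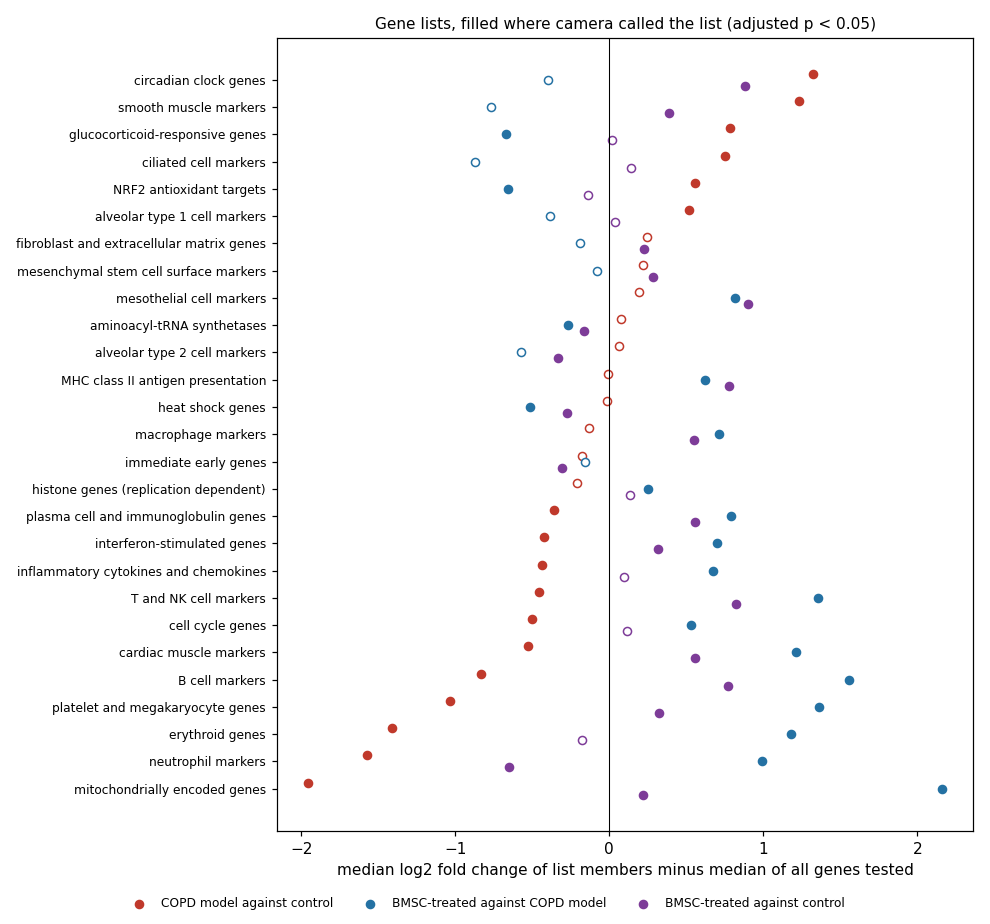
Median log2 fold change of the members of each gene list minus the median of all genes tested (horizontal axis), for the 27 lists called in at least 1 of the 3 comparisons (colours), filled where camera called the list. Mitochondrially encoded genes lie at -1.95 for COPD model against control and at 2.16 for BMSC-treated against COPD model.

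The second comparison asked what BMSC injection changed in the model. Scgb1a1 fell from 212700 ± 47100 to 24970 ± 13900 FPKM (SD, n = 3), a log2 change of -3.29 ± 0.37 (SE). Ptgs2, which encodes the inducible cyclooxygenase (chromosome 1, 150100031 to 150108234), fell from 13.8 ± 1.50 to 1.08 ± 0.47 FPKM, a log2 change of -2.84 ± 0.64. Upk1a, a uroplakin (chromosome 7, 30603092 to 30612734), was at 1.72, 2.11 and 3.22 FPKM in the COPD model and listed at 0 in all BMSC-treated libraries. The mitochondrial genes rose, mt-Nd5 by a log2 change of 1.81 ± 0.38, mt-Nd4l by 1.68 ± 0.40, mt-Atp8 by 1.54 ± 0.32 and mt-Co1 by 1.42 ± 0.30. Ugt1a5 was listed at 0, 2.14 and 0 FPKM after BMSCs. Ugt1a1 and Ugt1a2 were also called lower, but each had a COPD model library listed at 0. By limma 15 genes passed at an adjusted p under 0.05. The 8 higher were all mitochondrial, and the 7 lower were those named and the predicted gene Gm17606. The adjusted p was 4.31e-10 for Scgb1a1 and ranged from 0.0167 to 0.0419 for the others. As in the first comparison, the error of Scgb1a1 was borrowed from other abundant genes, with a moderated SD of 0.46 log2 against a pooled SD of 1.37 within groups.

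The median log2 change of all genes was -0.75, with 5.9% of genes above 0. Beside that shift, 1271 genes were lower and 36 higher at an unadjusted p under 0.05 and at least 1.5-fold, and 3682 genes (31.3%) had groups that did not overlap, 3650 of them lower and 32 higher, against 10% by chance. Genes of smallest p that did not pass included Map3k7cl, with 0.126 ± 0.219 FPKM against 1.88 ± 0.43 (adjusted p = 0.0648, limma), and Chtf8, with 1.32 ± 1.16 against 12.2 ± 2.85 (adjusted p = 0.0897, limma). With rescaled FPKM 0 of the 15 genes passed, and the log2 change was -2.34 for Scgb1a1 (adjusted p = 0.622, limma) and -2.13 for Ptgs2 (adjusted p = 0.52, limma). The mitochondrial changes grew, to 2.76 for mt-Nd5 and 2.37 for mt-Co1 (adjusted p = 0.622 each, limma). Without control 1 and BMSC-treated 1, 10 genes passed, of which Scgb1a1 and Ptgs2 were shared with the 15. Leaving out 1 library at a time gave 0 calls without BMSC-treated 1, 4 without BMSC-treated 2 or COPD model 3, 9 without COPD model 2, 13 to 20 without control 2, COPD model 1 or BMSC-treated 3, 24 without control 3 and 35 without control 1. Scgb1a1 lost its call without BMSC-treated 1 (adjusted p = 0.841, limma), and Ptgs2 without any 1 library other than control 1, control 3 and BMSC-treated 3 (0.0541 to 0.36). Upk1a lost it without COPD model 2 or 3 or any BMSC-treated library (0.06 to 0.926), and mt-Nd5 without COPD model 3, BMSC-treated 1 or BMSC-treated 2 (0.105, 0.926 and 0.155). Over all alternatives the adjusted p of limma ranged from 1.31e-36 to 0.841 for Scgb1a1 with 13 of 21 passing, from 0.00089 to 0.52 for Ptgs2 with 8 of 21, from 0.000479 to 0.926 for Upk1a with 6 of 20 and from 0.000213 to 0.926 for mt-Nd5 with 9 of 21.

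Of 39 lists, 19 were called by camera in BMSC-treated against COPD model, 15 above other genes and 4 below. The mitochondrial genes had a median 2.16 log2 above that of all genes (adjusted p = 5.97e-64, camera), with 7 of 12 passing over all genes and 11 over the list alone. Lymphoid lists came next. B cell markers lay 1.56 above (adjusted p = 4.34e-15, camera, and adjusted p = 0.0919 with an estimated correlation), with Cd79a, a signalling chain of the B cell receptor, at 18.7 ± 22.6 FPKM against 4.11 ± 3.92. T and NK cell markers lay 1.36 above (adjusted p = 1.15e-19, camera, and adjusted p = 0.0919 with an estimated correlation), with Cd3e, a chain of the T cell receptor complex, at 2.28 ± 0.10 FPKM against 0.861 ± 0.340, and Gzmb, a granzyme of cytotoxic cells, at 3.00 ± 2.84 against 0.603 ± 0.601. Platelet genes lay 1.36 above (adjusted p = 3.24e-20, camera, and adjusted p = 0.0919 with an estimated correlation), with Gp9 at 26.6 ± 14.2 FPKM against 6.35 ± 3.25. Erythroid genes lay 1.18 above (adjusted p = 5.07e-08, camera, and adjusted p = 0.0919 with an estimated correlation), with Hba-a1 at 301.8 ± 139.2 FPKM against 169.5 ± 129.1, and neutrophil markers 0.99 above (adjusted p = 6.48e-10, camera, and adjusted p = 0.147 with an estimated correlation), with S100a9 at 114.4 ± 36.7 against 79.0 ± 37.0. Interferon-stimulated genes lay 0.70 above (adjusted p = 9.7e-11, camera), with Cxcl9 at 3.59 ± 1.81 FPKM against 0.509 ± 0.496, the single member that passed over the list alone. Cytokines and chemokines lay 0.67 above (adjusted p = 3.27e-07, camera), although the member that passed over the list alone, Csf2, which encodes a myeloid growth factor, was lower at 0.22 ± 0.218 FPKM against 1.50 ± 0.74. MHC class II genes lay 0.62 above (adjusted p = 3.09e-06, camera, and adjusted p = 0.388 with an estimated correlation), with Cd74 at 340.9 ± 265.0 FPKM against 193.1 ± 61.5. Macrophage markers (0.71 above, adjusted p = 0.00583, camera), cardiac muscle (1.21, 2.86e-08), mesothelial markers (0.81, 0.000988), plasma cell genes (0.79, 0.000451), cell cycle genes (0.53, 0.00556) and histone genes (0.25, 0.00933) also ranked above other genes. In that order their adjusted p with an estimated correlation was 0.529, 0.211, 0.439, 0.187, 0.529 and 0.571. For interferon-stimulated, cytokine, MHC class II, macrophage, cell cycle and histone genes the list's own median lay below 0, and only its distance from the falling median of all genes was positive. The log2(FPKM + 1) scale holds the changes of low genes toward 0, which would rank such genes above a falling median.

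The 4 lists that ranked below other genes were NRF2 targets, glucocorticoid-responsive genes, heat shock genes and aminoacyl-tRNA synthetases. NRF2 targets lay 0.66 log2 below (adjusted p = 0.00108, camera, and adjusted p = 0.697 with an estimated correlation), and 5 of 15 passed over the list alone, all lower, among them the glutathione transferases Gsta2 (log2 change -2.55 ± 0.72), Gsta1 (-1.34 ± 0.41) and Gsta4 (-2.44 ± 0.82) and Gclc (-2.07 ± 0.80), the catalytic subunit for glutathione synthesis. Glucocorticoid-responsive genes lay 0.67 below (adjusted p = 0.00415, camera, and adjusted p = 0.505 with an estimated correlation), with 4 of 9 passing over the list alone, among them Fkbp5, at 1.26 ± 0.80 FPKM against 6.86 ± 3.26, and Pdk4, at 1.53 ± 0.20 against 8.08 ± 1.71. Heat shock genes lay 0.52 below (adjusted p = 0.0118, camera, and adjusted p = 0.703 with an estimated correlation), with 4 of 9 passing over the list alone, among them Hspa1b (-1.79 ± 0.60), Hspa1a (-1.56 ± 0.57) and Hsph1 (-1.86 ± 0.73). The synthetases, which charge tRNAs, lay 0.27 below (adjusted p = 0.0221, camera, and adjusted p = 0.791 with an estimated correlation), with 0 of 18 passing over the list alone and Cars at 5.10 ± 0.46 FPKM in the COPD model and 1.44 ± 1.09 after BMSCs.

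With an estimated correlation the mitochondrial, interferon-stimulated and cytokine calls held, each at an adjusted p of 0.0286. The other 16 of the 19 calls were lost. fry called 0 of 39 lists (smallest adjusted p 0.518). Rescaled FPKM ended the calls of mesothelial markers (adjusted p = 0.25), glucocorticoid-responsive (0.0863), cell cycle (0.0503), heat shock (0.0894) and synthetase genes (0.0622), and fits without control 1 and BMSC-treated 1 those of erythroid genes (0.0946), cell cycle (0.0599) and synthetases (0.0564). Of single libraries, BMSC-treated 1 ended the calls of cell cycle (0.0649 without it) and erythroid genes (0.102), and BMSC-treated 3 those of glucocorticoid-responsive genes (0.128), macrophages (0.108) and mesothelial markers (0.0673). COPD model 1 ended those of heat shock genes (0.0733) and mesothelial markers (0.173), COPD model 3 those of synthetases (0.054) and histones (0.116), and control 1, through the shared spread, those of synthetases and histones (0.0517 each).

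The third comparison set BMSC-treated lungs against control. limma called 0 of 11765 genes (smallest adjusted p 0.561), and at an unadjusted p under 0.05 and at least 1.5-fold 33 were higher and 15 lower. The groups did not overlap in 66 genes (0.6%). The 10% given by chance holds for independent libraries, and the libraries of these groups deviated together by number, so the 2 shares cannot be compared. Genes of smallest p included Rbp7, a retinol-binding protein, at 0.231 ± 0.282 FPKM against 4.53 ± 1.54 in control (log2 change -2.15 ± 0.53). Among them were also Sp1, a transcription factor, at 4.74 ± 2.91 against 0.269 ± 0.067, the chemokine Ccl4 at 1.99 ± 1.91 against 0.0954 ± 0.165, and Dbp, with a log2 change of 2.57 ± 0.78. The adjusted p was 0.561 for Rbp7 and 1.0 for the other 3 (limma). Scgb1a1, mt-Co1 and Plagl1 were not called, with 24970 ± 13900, 52570 ± 18670 and 1.98 ± 1.33 FPKM against 55590 ± 46700, 52770 ± 22620 and 0.386 ± 0.123 in control. Same-numbered control and BMSC-treated libraries deviated together. A fit of all 9 libraries with the replicate number as a block also called 0 genes. It blocked the COPD model libraries as well, and no paired fit of control and BMSC-treated libraries alone was run. Without control 1 and BMSC-treated 1, 6 genes passed, Rbp7, Dbp and Hsph1 among them. Without control 1 alone 2 passed, Scgb1a1 and Gm20521, and without BMSC-treated 3 Gm20521 passed.

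In the same comparison 19 of 39 lists were called by camera, 14 above other genes and 5 below, and with an estimated correlation 0 of the 19 held. T and NK cell markers lay 0.82 log2 above (adjusted p = 3.58e-16, camera, and adjusted p = 0.392 with an estimated correlation), with the log2 changes of all 11 members above 0 and 0 of 11 passing over the list alone. Those of Gzmb, Cd8a and Ccl5 were 1.10 ± 0.42, 0.97 ± 0.45 and 1.25 ± 0.76, with p values adjusted over the list alone of 0.112, 0.195 and 0.282 (limma). Circadian genes lay 0.88 above (adjusted p = 4.66e-14, camera, and adjusted p = 0.423 with an estimated correlation), with 1 of 13, Dbp (2.57 ± 0.78), passing over the list alone. MHC class II genes lay 0.78 above (adjusted p = 1.24e-09, camera), B cell markers 0.77 above (1.13e-06), mesothelial markers 0.90 above (8.43e-06) and interferon-stimulated genes 0.31 above (8.01e-07). With an estimated correlation their adjusted p was 0.214 for interferon-stimulated genes and 0.423 for the other lists. The lung mesothelial antigen Msln stood at 11.9 ± 10.7 FPKM against 3.26 ± 3.29. Also above were cardiac muscle (0.56, adjusted p = 0.000106, camera), macrophage (0.55, 0.00285), platelet (0.32, 0.00812), smooth muscle (0.39, 0.0126) and mitochondrial genes (0.22, 0.0223), mesenchymal stem cell surface markers (0.28, 0.0395), plasma cell genes (0.56, 0.0439), and fibroblast and matrix genes (0.23, 0.0495). In that order their adjusted p with an estimated correlation was 0.528, 0.571, 0.742, 0.742, 0.891, 0.891, 0.571 and 0.946. Nppa, the atrial natriuretic peptide gene, was the single cardiac member to pass over the list alone (1.42 ± 0.46). Of the 11 mesenchymal surface markers, 8 had log2 changes above 0 and 3 below, and 0 passed over the list alone. Pdgfrb stood at 13.3 ± 10.7 FPKM against 4.53 ± 4.14, with 12.6 ± 4.15 in the COPD model without BMSCs, and Thy1 at 5.15 ± 3.67 against 3.25 ± 3.25, while Cd44 stood at 9.49 ± 7.25 against 12.9 ± 8.03 and Eng at 15.6 ± 12.6 against 16.1 ± 5.28. Neutrophil markers lay 0.65 below (adjusted p = 6.04e-06, camera, and adjusted p = 0.423 with an estimated correlation), with S100a8 at 73.6 ± 19.9 FPKM against 227.4 ± 151.1. Heat shock genes (0.27 below, adjusted p = 0.000306, camera), immediate early genes (0.31, 0.00706), alveolar type 2 markers (0.34, 0.0495) and synthetases (0.16, 0.0495) also ranked below, with adjusted p values of 0.573, 0.74, 0.896 and 0.969 with an estimated correlation. Hsph1 stood at 2.94 ± 2.08 FPKM against 15.5 ± 13.4, Fos at 4.00 ± 1.07 against 7.99 ± 2.81 and Sftpb, a surfactant protein, at 238.9 ± 134.7 against 455.5 ± 313.6.

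In this comparison fry called 0 of 39 lists (smallest adjusted p 0.995). With the replicate block the adjusted p of camera was 0.0731 for plasma cells, 0.0748 for fibroblasts, 0.052 for alveolar type 2 and smooth muscle and 0.0525 for mesenchymal surface markers, and the other 14 calls held. The T and NK cell, circadian, MHC class II and mesothelial calls held without any 1 library. Rescaled FPKM ended the calls of neutrophils (adjusted p = 0.06), smooth muscle (0.119), alveolar type 2 and fibroblast (0.163 each), mitochondrial (0.283) and plasma cell genes (0.298). Fits without control 1 and BMSC-treated 1 ended those of neutrophils (0.115), synthetases (0.271), immediate early and mitochondrial genes (0.357 each) and platelets (0.97). Leaving out control 1 alone ended 8 calls, some of them the same, with adjusted p values of 0.905 with the direction turned for neutrophils, 0.572 for platelets, 0.362 for fibroblasts, 0.253 for plasma cells, 0.158 for mesenchymal surface markers, 0.135 for synthetases, 0.117 for cardiac muscle and 0.0884 for immediate early genes. Without control 2 they were 0.821 for alveolar type 2 and 0.348 for smooth muscle, both turned, 0.873 for fibroblasts, 0.281 for mitochondrial genes, 0.212 for synthetases and 0.0749 for neutrophils. Without control 3 they were 0.876 for cardiac muscle, 0.183 for plasma cells, 0.172 for interferon-stimulated genes, 0.159 for macrophages, 0.112 for immediate early genes, platelets and synthetases, 0.0833 for heat shock genes, 0.0649 for B cells and 0.0605 for mesenchymal surface markers, and the mitochondrial list passed in the other direction (0.000748). Without BMSC-treated 1 the mitochondrial list again passed in the other direction (1.61e-07), and the adjusted p was 0.494 for synthetases, 0.342 for platelets, 0.274 for interferon-stimulated genes and 0.252 for alveolar type 2 and immediate early genes. Without BMSC-treated 2 it was 0.849 for smooth muscle and mesenchymal surface markers, 0.133 for plasma cells and 0.0791 for fibroblasts, and without BMSC-treated 3 0.679 for fibroblasts, 0.598 for alveolar type 2, 0.241 for plasma cells, 0.0964 for macrophages, 0.0754 for B cells and 0.0671 for mesenchymal surface markers. Without a COPD model library the synthetase and fibroblast lists lay at 0.0502 to 0.0524 where they missed the threshold.

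In none of the 3 comparisons did camera call 12 of the 39 lists tested. The smallest adjusted p over the 3 was 0.0566 for proteases and their inhibitors, 0.0715 for lipid and sterol synthesis, 0.0603 for skeletal muscle, 0.109 for adipocyte markers, 0.121 for aryl hydrocarbon receptor targets, 0.116 for nuclear oxidative phosphorylation genes and 0.115 for cytosolic ribosomal proteins. It was 0.204 for endothelial markers, 0.22 for sex-linked genes, 0.298 for p53 targets, 0.296 for tRNA cleavage and modification enzymes and 0.45 for club and goblet cell markers. The club and goblet list held 11 tested genes, of which Scgb1a1 was called in the first and second comparisons. Over the list alone Cbr2, a carbonyl reductase of club cells, also passed in both, with 4218 ± 169.2 FPKM in the COPD model against 1964 ± 1641 in control and 1566 ± 1145 after BMSCs (SD, n = 3), log2 changes of 1.79 ± 0.61 and -1.83 ± 0.61. Its adjusted p over all genes was 0.514 and 0.375 (limma), and 2 members in the first comparison and 4 in the second passed over the list alone. Without control 1 and BMSC-treated 1 the log2 change of Cbr2 in the first comparison was 0.62. Scgb3a2, another secretoglobin of club cells that was named after its values were seen, stood at 1712 ± 1384 FPKM in control, 3447 ± 1963 in the COPD model and 1118 ± 809 after BMSCs, with the same adjusted p values over all genes.

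The design also asked whether BMSCs moved the genes changed in the model back. Of the 9 genes called in COPD model against control and the 15 called in BMSC-treated against COPD model, 6 were shared and all 6 moved in opposite directions: Scgb1a1 and Ugt1a5 up and then down, mt-Co1, mt-Nd4, mt-Nd5 and mt-Cytb down and then up. Independent lists of these sizes would share 0.00238 genes up and then down and 0.0034 down and then up. Because both comparisons use the same COPD model libraries, opposite changes arise without any effect. Over the 11765 genes the correlation of the 2 log2 changes was -0.80, where 100 simulations with no effect gave -0.50 (-0.524 to -0.478). The share of genes with opposite signs, 95.4%, follows from the shift of all genes, with 94.4% above 0 in the first comparison and 5.9% in the second, and decides nothing. The covariance was -0.17 against -0.19 simulated, a difference of 0.02. These simulations took the groups as independent, whereas same-numbered control and BMSC-treated libraries deviated together. A further 100 simulations that kept these pair correlations, chosen after the values were seen, gave a correlation of -0.72 (-0.731 to -0.71) and a covariance of -0.27, with genes drawn independently of each other. Neither set of simulations held the shift of all genes, which log2(FPKM + 1) spreads unevenly over low and high genes. The observed correlation therefore does not decide whether BMSCs moved genes back. Part of the overlap may be due to the shared libraries, which could not be split. Without control 1 and BMSC-treated 1 and with rescaled FPKM, 0 genes were called in opposite directions, and leaving out 1 library gave 0 without BMSC-treated 1, 1 without control 1 or control 2, 2 without COPD model 3, 3 without COPD model 2 or BMSC-treated 2, 11 without COPD model 1 or BMSC-treated 3 and 21 without control 3.

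The tsRNA pool of the lung consisted mainly of fragments from the 5' part of glycine tRNAs. By structural type, tRF-5c, fragments that start at the 5' end of the mature tRNA, made up 84.8% of all counts (66.3% to 89.3% per library), tiRNA-5, the longer 5' fragments left by cleavage in the anticodon loop, made up 8.02% and the shorter tRF-5b 6.81%. Fragments from glycine tRNAs held 84.9% of counts, those of mitochondrial serine tRNA 7.22%, of glutamate 4.4% and of lysine 2.2%. The most abundant single tsRNA was tRF-1:32-Gly-GCC-2-M3 (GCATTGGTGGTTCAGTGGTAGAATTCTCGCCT), with 39.7% of counts. A set of 46 tsRNAs came from mitochondrial tRNAs, and they held 10.4% ± 7.46 of counts in control, 7.6% ± 3.02 in the COPD model and 11.9% ± 10.1 in BMSC-treated libraries (SD, n = 3). Exact permutation p values for this share were 0.6, 0.7 and 0.7 for the 3 comparisons, two-sided and unpaired, and between same-numbered control and BMSC-treated libraries the exact paired p was 0.5. The shallowest library of each group had the highest mitochondrial share, 19.0% in control 2, 11.1% in COPD model 3 and 23.5% in BMSC-treated 2, against 5.08% to 7.24% in the others.

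**Figure D4:**
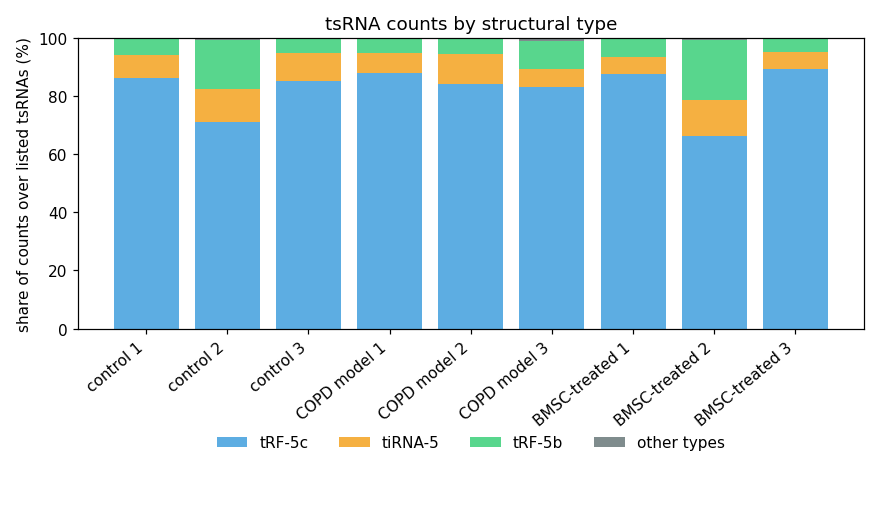
Share of the listed tsRNA counts of each library (vertical axis, percent) by structural type, for the 9 tsRNA libraries (bars). tRF-5c holds between 66.3% and 89.3% of the counts in each library.

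In COPD model against control edgeR's quasi-likelihood test called 0 of 191 tsRNAs at an adjusted p under 0.05, with a smallest adjusted p of 0.0603. At an unadjusted p under 0.05 and at least 1.5-fold, 9 were higher and 2 lower, and DESeq2 called 2. Those 2 were also the tsRNAs of smallest p by edgeR. For single tsRNAs the CPM are given as deposited, while the log2 changes come from counts with TMM factors, so the 2 can differ. tRF-+1:T15-iMet-CAT-1 (TCGGAGGCTTTGTTT), a 15-nucleotide fragment from the 3' trailer of an initiator methionine tRNA precursor, had 56.7 ± 35.1 CPM (SD, n = 3) in the COPD model against 9.02 ± 3.76 in control, from 43 to 100 counts against 11 to 26 per library (log2 change 2.71 ± 0.73, SE). tRF-+1:T16-iMet-CAT-1, which is 1 nucleotide longer, had 50.3 ± 28.1 CPM against 8.22 ± 1.57 (log2 change 2.57 ± 0.70). On the lower side, tRF-1:16-chrM.Glu-TTC (GTTTCTGTAGTTGAAT), from the 5' end of mitochondrial glutamate tRNA, had 4.34 ± 1.80 CPM against 19.9 ± 3.64 (log2 change -2.13 ± 0.76, adjusted p = 0.352), from 4 to 10 counts against 35 to 47. Fragments of 15 and 22 nucleotides from mitochondrial glutamine tRNA, tRF-1:15-chrM.Gln-TTG and tRF-1:22-chrM.Gln-TTG, had log2 changes of -1.29 ± 0.63 and -1.16 ± 0.59 (adjusted p = 0.758 each, edgeR). The groups did not overlap in 26 tsRNAs (13.6%), against 10% by chance. Leaving out control 2, COPD model 1 or COPD model 2 gave 3 calls each and leaving out BMSC-treated 2 gave 2, all of them higher trailer fragments of initiator methionine or threonine tRNAs.

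In BMSC-treated against COPD model edgeR again called 0 of 191 tsRNAs, with a smallest adjusted p of 0.0636, and DESeq2 called 1. At an unadjusted p under 0.05 and at least 1.5-fold 9 were higher and 16 lower. The fragment that DESeq2 called was tRF-1:16-chrM.Glu-TTC, with 27.7 ± 18.0 CPM against 4.34 ± 1.80 (log2 change 2.72 ± 0.77). tRF-1:15-chrM.Gln-TTG had 292.8 ± 216.9 CPM against 72.3 ± 26.5 (log2 change 2.05 ± 0.64, adjusted p = 0.0873, edgeR). Trailer fragments of a threonine tRNA precursor, tRF-+1:T30-Thr-CGT-1, tRF-+1:T31-Thr-CGT-1 and tRF-+1:T32-Thr-CGT-1, had log2 changes of -3.38 ± 0.87, -3.07 ± 0.86 and -2.99 ± 0.89. That difference came from 1 library: tRF-+1:T30-Thr-CGT-1 stood at 211.6 CPM in COPD model 3, against 10.3 and 10.8 in the other COPD model libraries and 1.88 to 12.1 after BMSCs. The groups did not overlap in 23 tsRNAs (12%). With relative log expression factors in place of trimmed means 5 tsRNAs were called, and leaving out 1 library gave 0 to 6, with 6 without control 2, 4 without COPD model 2 or BMSC-treated 2, 3 without control 1 or COPD model 1 and 2 without BMSC-treated 3.

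**Figure D5:**
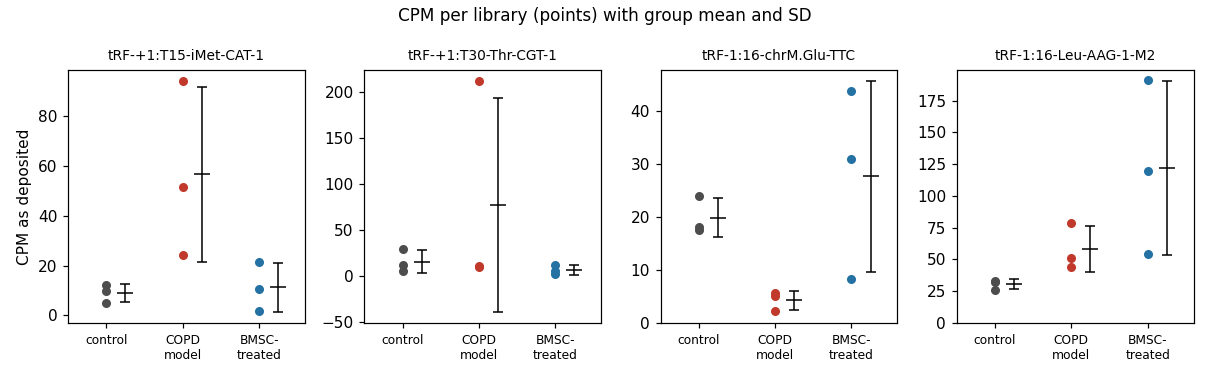
CPM of 4 tsRNAs (vertical axes) in the 9 tsRNA libraries by group, with points for libraries and bars for the group mean and SD. The tRF-+1:T30-Thr-CGT-1 fragment reaches 211.6 CPM in COPD model 3, and the mitochondrial glutamate fragment lies between 2.28 and 5.6 CPM in the COPD model libraries.

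In BMSC-treated against control edgeR called 0 of 191 tsRNAs, with a smallest adjusted p of 0.1, and DESeq2 called 1, tRF-1:16-Leu-AAG-1-M2 (GGTAGCGTGGCCGAGC), a fragment from the 5' end of a leucine tRNA. It had 121.6 ± 68.5 CPM as deposited against 30.4 ± 4.04 in control. With TMM factors it had 252.6 ± 188 against 49.0 ± 3.94 CPM (log2 change 2.36 ± 0.63). The related tRF-1:16-Leu-AAG-2-M3 had 43.1 ± 1.99 CPM as deposited against 14.2 ± 7.02 (log2 change 1.89 ± 0.65, adjusted p = 0.57, edgeR). At an unadjusted p under 0.05 and at least 1.5-fold 4 tsRNAs were higher and 3 lower, and the groups did not overlap in 13 (6.8%). The fit with the replicate number as a block, which blocked the COPD model libraries as well, also called 0. Without BMSC-treated 2, edgeR called 1, the leucine fragment.

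Counts were also summed by the 9 structural types and by the 32 parent tRNA classes. edgeR called 2 such classes, both higher in BMSC-treated than in COPD model libraries. The tRF-5a type, the shortest fragments from the 5' end, had 1744 ± 240.3 normalised CPM against 738.1 ± 144.3 (SD, n = 3), a log2 change of 1.24 ± 0.33 (adjusted p = 0.0215), with 932.3 ± 122.8 in control. The mitochondrial glutamate class, which holds the single fragment above, had a log2 change of 2.71 ± 0.68 (adjusted p = 0.0257). No class was called in the other comparisons, where 0 and 1 types and 3 and 1 parent tRNA classes had an unadjusted p under 0.05. Both calls were lost with library size alone in place of TMM factors or with library sizes implied by the CPM, and the mitochondrial glutamate call was lost without the shallowest library of each group, where 2 classes were called. Leaving out 1 library gave 0 to 4 calls, with 0 without control 3, BMSC-treated 1 or BMSC-treated 2. Without control 1 the mitochondrial glutamate class alone was called, and without COPD model 1 neither of the 2 was, but threonine was called lower. Without COPD model 2 mitochondrial glutamate and threonine were called and tRF-5a was lost, and without BMSC-treated 3 the 2 reported classes and those of mitochondrial glutamine and isoleucine were called, both higher.

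For tsRNAs the reversal had 0 called members, and 9 tsRNAs had an unadjusted p under 0.05 in both comparisons with opposite signs. Over the 191 tsRNAs the correlation of the log2 changes of COPD model against control and of BMSC-treated against COPD model was -0.74, where 100 simulations with no effect gave -0.50 (-0.63 to -0.36). Opposite signs were seen in 75.4% of tsRNAs against 66.8% simulated, with 73.8% at most. The covariance was -0.53 against -0.25 simulated, a difference of -0.28. With the pair correlations of control and BMSC-treated libraries kept, 100 simulations gave a correlation of -0.77 (-0.848 to -0.667), 78.2% with opposite signs and a covariance of -0.38, so the observed correlation and share lay within what no effect gives. tsRNAs are not independent replicates, and the shared COPD model libraries could not be split into parts of at least 2 libraries.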

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

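The fits without control 1 and BMSC-treated 1, the rescaled FPKM, the tsRNA fits without the shallowest library of each group and those with it as a covariate were chosen after seeing the data. Called numbers of genes are given for COPD model against control, BMSC-treated against COPD model and BMSC-treated against control, against 9, 15 and 0 as reported, with 6 genes reversed. What depth limits in the mRNA data is unknown, and in the tsRNA data the initiator methionine and mitochondrial glutamate fragments rested on 4 to 100 counts per control or COPD model library. Where a fit changed a count, the cause was not tested, except that fits of fewer libraries have fewer residual degrees of freedom. When 1 library of a group was left out, the pooled spread over all groups was used.

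Pseudocounts of 0.1 and of 0.01 left 0 and 0 genes called in the first and second comparisons, with 0 reversed at 0.1. Without a filter on low FPKM 1 and 6 were called, and with a mean FPKM of at least 5, 1 and 1, the single gene being Scgb1a1 each time. Quantile normalization left 0 and 0, with 0 reversed, and centring on the median 0 and 0. These scalings move the median of all genes in the first comparison from 0.66 to 0.003 with quantiles and to 0.143 with rescaled FPKM, and a pseudocount of 0.1 moves it to 0.924. With only the 6 libraries compared 2 were called in the first comparison, and with robust moderation 4 in the second. Rescaled FPKM left 0 and 0, with 0 reversed. Without control 1 and BMSC-treated 1 there were 3 in the first and 6 in the third, with 0 reversed, and with both changes together 0, 4 and 3. The 4 were Ptgs2, Chtf8, Pttg1ip and Cadm1 and the 3 were Hsph1, Chtf8 and Pttg1ip, where Pttg1ip and Cadm1 were named after their values were seen. At an unadjusted p under 0.05 and at least 1.5-fold there were 775, 1307 and 48, with 457 reversed, and at an adjusted p under 0.1 there were 16 in the first. Leaving out each library gave 1 to 47, 0 to 35 and 0 to 2 genes, and 0 to 21 reversed. Of the values of named genes under all alternatives, 7062 kept their direction and side of the threshold, 291 lost a call and 63 gained one. A further 241 changed direction without passing in either fit, and 0 changed direction where either fit passed. Many named genes were not called in the reported test, so for them a kept side means staying uncalled.

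For gene lists, an estimated correlation left 4, 3 and 0 calls of 17, 19 and 19, and fry called 0, 0 and 0. Leaving out each library gave 16 to 20, 18 to 24 and 11 to 20. Of the values of lists called in the reported test, 678 kept direction and side, 238 lost a call and 19 reversed. In COPD model against control ciliated markers turned without control 1 and BMSC-treated 1 (adjusted p = 0.669), with rescaled FPKM as well (0.3003) and without control 1 (0.578), and cardiac muscle without control 2 (0.0503). Over all left-out libraries their adjusted p ranged from 3.19e-05 to 0.578 and from 5.69e-07 to 0.114. In BMSC-treated against control neutrophil markers turned without control 1 (0.905), alveolar type 2 markers (0.821) and smooth muscle (0.348) without control 2, and mitochondrial genes without control 3 (0.000748) or BMSC-treated 1 (1.61e-07). In the same order their adjusted p ranged over all left-out libraries from 2.3e-32 to 0.905, 0.000343 to 0.821, 5.33e-09 to 0.849 and 2.22e-19 to 0.281. fry, which does not set a list against the shifted median of all genes, gave the other direction in the first comparison for cytokines (0.789), plasma cells (0.867), T and NK cells (0.837), cardiac muscle (0.867), interferon-stimulated (0.591) and cell cycle genes (0.702). In the second it did so for macrophages (0.859), mesothelial markers (0.982), cell cycle (0.785) and histone genes (0.863). Calls that held with an estimated correlation, with rescaled FPKM and without control 1 and BMSC-treated 1 each numbered 4, 11 and 15 in the first comparison, 3, 14 and 16 in the second and 0, 13 and 14 in the third. Over its 17 alternatives the circadian list passed in 15 in the first comparison, the neutrophil list in 16 and the T and NK cell list in 10.

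For tsRNAs, against 0 calls in each comparison and 2 classes as reported, BMSC-treated against COPD model had 5 with relative log expression factors, 2 with library sizes implied by the CPM, 4 with at least 10 CPM in 3 libraries and 3 with only the 6 libraries compared, each set including tRF-+1:T30-Thr-CGT-1 and tRF-+1:T31-Thr-CGT-1. DESeq2 called 2, 1 and 1, and limma on log2(CPM + 1) 0 in each. An unadjusted p under 0.05 and at least 1.5-fold gave 11, 25 and 7, with 9 reversed. Without the shallowest library of each group 3 were called in BMSC-treated against control. With it as a covariate 2 and 11 were called in the first and second comparisons, with 1 reversed and 10 classes. Library size alone and sizes implied by the CPM left 0 classes. Leaving out each library gave 0 to 3, 0 to 6 and 0 to 1 tsRNAs, 0 to 4 classes and 0 to 3 reversed. Of the values of named tsRNAs, which the reported test did not call, 299 kept direction and side and 60 passed. A further 1 changed direction without passing, and 0 changed direction where either fit passed.

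With the replicate number as a block, 17, 34 and 0 genes were called, of which 5 and 10 were among the 9 and 15 reported, and 13 were reversed. All groups were blocked in this fit, the COPD model libraries included. The block called 1 tsRNA in the first comparison and 3 in the second. In the first comparison Scgb1a1 (adjusted p = 0.0702, limma), Ugt1a5 (0.0942) and Ugt1a9 (0.127) lost their calls with the block, and in the second Upk1a (0.0622), Ugt1a5 (0.0698), Ugt1a1 and Ugt1a2 (0.0706 each). Of the 2 classes it kept mitochondrial glutamate, ended tRF-5a and called threonine, lower in the second comparison. It ended the calls of ciliated markers (0.244) and smooth muscle (0.325) in the first comparison and of heat shock genes (0.129) in the second, and it changed no call of BMSC-treated against control other than those given beside that comparison. Same-numbered libraries of the first comparison had correlated deviations of -0.02, 0.18 and -0.17 for mRNA and 0.47, -0.6 and -0.52 for tsRNA. Those of the second had 0.05, -0.06 and -0.1 and 0.54, -0.36 and -0.08, so the numbers were not taken to pair the libraries of these 2 comparisons. Not every library correlated best with its own number in these 2 comparisons. In BMSC-treated against control each did for mRNA, but for tsRNA number 3 (0.2) correlated best with number 1. The mitochondrial share of FPKM nevertheless fell from number 1 to number 3 in every group. It was 89.25%, 65.08% and 46.92% in control, 30.04%, 28.31% and 23.91% in the COPD model and 92.24%, 70.79% and 55.63% after BMSCs. An order by number common to all groups therefore cannot be excluded.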

Other observations

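All tests of explanations below were chosen only after the result was seen, except the time of day test, and the other splits of the libraries had been planned.

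Several lists of interest in smoke-exposed lung were not called, and their leading members are given as values (SD, n = 3). Among aryl hydrocarbon receptor targets, which respond to compounds of smoke, Cyp1b1 stood at 2.82 ± 2.51 FPKM in control, 5.70 ± 2.42 in the COPD model and 1.32 ± 0.68 after BMSCs, and Nqo1, a quinone reductase, at 3.92 ± 2.62, 10.6 ± 5.26 and 4.95 ± 2.82. All 5 tested targets lay above the median of all genes in the COPD model (0.41 log2 for the list, adjusted p = 0.121, camera). After BMSCs 2 of them were lower when adjusted over the list alone. Hmgcs1, a sterol synthesis gene, had 12.0 ± 7.07 FPKM in control, 31.1 ± 3.47 in the COPD model and 10.1 ± 6.71 after BMSCs. Among enzymes of tRNA cleavage and modification, Elac2, which cleaves 3' trailers from tRNA precursors, had 1.05 ± 0.75 FPKM in control, 3.19 ± 1.28 in the COPD model and 1.06 ± 0.76 after BMSCs (adjusted p = 0.514 and 0.375, limma). The Y-linked genes Ddx3y and Eif2s3y were detected in all groups, with means of 8.86 to 20.7 and 6.29 to 17.9 FPKM.

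Scgb1a1 was higher in the COPD model libraries than in the other 6. A smaller mitochondrial share does not account for all of it: with FPKM rescaled over the other genes, the 3 COPD model libraries still lay above the other 6, with 189700, 179100 and 113800 against 15540 to 83080, a difference of 2.09 log2. The call itself ended, from 2.62 ± 0.37 to 1.85 ± 0.71 log2 against control (adjusted p = 0.755, limma). The change shrank and the moderated SD rose from 0.46 to 0.87, and their separate parts in the lost call were not tested. More club cells in the sampled pieces would raise other club cell genes by about as much. The other 10 markers tested with Scgb1a1 mix club and goblet cell genes, so their median tests this only in part. That median moved by at most 18.1% of the change of Scgb1a1, 0.35 against 1.96 and -0.13 against -2.53 relative to all genes (interquartile ranges 1.06 and 2.03). Of the 10, however, 7 and 6 moved in the direction of Scgb1a1, Cbr2 by 1.13 and -1.08 and Scgb3a2 by 0.98 and -1.05, so more club cells as part of the change stay open, as does, untested, an effect of smoke or BMSCs on Scgb1a1 itself.

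Circadian genes ranked above other genes in both smoke-exposed groups relative to control, with calls lost at an estimated correlation (adjusted p = 0.448 and 0.423, camera). With rescaled FPKM the list lay 1.21 and 0.91 log2 above all genes (adjusted p = 6.24e-07 and 4.19e-08, camera). Because the list is set against all genes, which a scaling moves nearly alike, these values had to stay close and do not test scaling. Glucocorticoid action in both groups is argued against by a glucocorticoid-responsive list at 0.02 in BMSC-treated against control (interquartile range 0.21), where the circadian list lay at 0.88. In COPD model against control the glucocorticoid-responsive list lay 0.78 above all genes, so glucocorticoid action in the COPD model group alone stays open. A different time of day at tissue collection is a candidate explanation. As medians, the 10 tested genes that peak with Dbp exceeded the 3 tested genes in antiphase by 2.33 log2 in the COPD model and by 1.61 after BMSCs. Of the 3, Cry1 stood at 1.12 ± 0.58 (SE) in the COPD model, with Clock at -0.66 ± 0.49 and Nfil3 at -0.22 ± 0.60. After BMSCs they stood at -0.03 ± 0.58, -0.79 ± 0.49 and -1.12 ± 0.60. Arntl and Npas2, also set down as antiphase genes, were not among the genes tested, so antiphase movement was tested only in part. The labels give no collection times, so a shift of the clock by smoke exposure stays open beside it.

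Ciliated cell genes were low in control 1 and BMSC-treated 1. Scaling by the mitochondrial share is argued against, since with rescaled FPKM both lay at least 1.11 log2 below the lowest of the other 7 libraries. Less conducting airway in the sampled piece may account for control 1, where ciliated and club lists lay -3.51 and -2.64 log2 from the mean of the other 7 and the farthest of the alveolar and endothelial lists -0.71. For BMSC-treated 1 the lists part and do not decide it: ciliated genes lay at -1.56 but club and goblet genes at 1, within the SD of the other 7, 1.32. Its rescaled Scgb1a1 was 30580 FPKM, near the low end of the 24470 to 189700 of the other 7. The test by library was chosen after the values were seen, and an earlier expectation that both libraries would be low in both airway lists was not met by BMSC-treated 1.

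Other splits of the libraries were counted. With 10 splits of 6 libraries no share under 0.05 can be reached. For genes, 1 of 10 splits gave as many calls in COPD model against control (9, highest other 8) and 1 of 10 in BMSC-treated against COPD model (15, highest other 8), while in BMSC-treated against control, where the real count of 0 makes all 10 splits as large and decides nothing, the highest other was 4387. That other split set control 1, control 2 and BMSC-treated 1 against the rest, which points to a structure of the samples. Among the 4 splits that part all 3 numbered pairs of these groups, the highest other called 0. For lists, 5 of 10, 3 of 10 and 1 of 10 splits gave as many (17, 19 and 19, highest other 19, 24 and 18, and 15 for the third among splits that part the pairs). For tsRNAs the real count was 0 in each comparison, so that all 10 splits gave as many and the counts decide nothing (highest other 3, 5 and 6, and 0 for the third among splits that part the pairs). Of 100 drawn splits into 3 groups, 9 gave as many reversed genes (6, highest other 4287) and 20 as many tsRNA classes (2, highest other 33), so for these chance cannot be excluded. All 100 gave as many reversed tsRNAs (0, highest other 33), as a real count of 0 must, which decides nothing.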
